A study of Corynebacterium glutamicum R with 2 samples.

How the data were processed

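RNA from the wild type and from an rsdA deletion mutant of Corynebacterium glutamicum R, a Gram-positive soil bacterium used for amino acid production, was compared on 2-colour oligonucleotide arrays. Per the labels' protocols, cultures grew at 33 °C in 100 ml of a rich medium with 1% glucose, cells were taken in the exponential phase, and 10 µg of total RNA per sample was reverse transcribed and labelled with a cyanine dye. Per the labels, each of the 2 arrays analysed here carried wild-type cDNA in Cy5 (red) and mutant cDNA in Cy3 (green). The series text describes 3 independent experiments; 2 arrays were analysed here, and were treated as 2 biological replicates. No array analysed here had the dyes exchanged, so a dye effect specific to a probe stays in every ratio.

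Per the file headers, the authors extracted the scans with Agilent Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 10.5.5.1. The deposited files give, per spot, the median intensity of each channel and of its local background, and processed intensities that Feature Extraction had background-subtracted and dye-normalized. The deposited files also hold a log10 ratio of red over green, which is wild type over mutant here. The files also hold other deposited values, which are flags of 0 or 1 per spot for background, outliers, saturation and controls. A value table holds the authors' deposited log2 ratios, 1 per probe. Its scale and direction were found by setting it against the scanner log10 ratios of the same array: r was 0.998 and 0.995 over the 3278 probes and the slope was 3.32 on both arrays, which is log2 of 10, so the table is log2 of wild type over mutant. Its column medians were 0.0027 and 0.0026. How its processing differed from that of the scanner ratios is not given in the sources used here.

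The array holds 6864 spots, of which 6556 belong to 3278 probes with 2 spots each, and 308 are control or empty spots. Probes carry only a running number (up to 3285), and nothing used here pairs a number with a gene of strain R; the gene table at hand is for another strain of the species and lists no probe numbers. The 21 gene lists fixed before the data were examined were therefore not tested, and the probes of rsdA and of the neighbouring sigma factor gene sigD are not reported. Probes, not genes, are the features throughout.

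The median spot intensities were corrected with normexp (limma 3.58.1 in R 4.3.3, offset 50, all spots) and normalized within each array by loess, with control and outlier-flagged spots at weight 0. The plan had named mean intensities, but only median ones were found in the files. The sign was turned so that a positive log2 ratio means higher in the mutant. The 2 spots of a probe were averaged after outlier-flagged spots (4 on array 1 and 21 on array 2) had been left out. No spot was saturated. Probes well above background at 1 or more spots, in at least 1 channel, on both arrays were tested, which left out 179 dim probes and 1 probe whose spots were all flagged on an array. The log2 ratios of the remaining 3098 probes were tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). With 2 arrays a probe has 1 residual degree of freedom, to which eBayes added 2.71 prior degrees of freedom. Because of this small number, probes at least 2-fold changed in the same direction on both arrays were also counted, without a test. Levels of single channels are loess values brought to a common scale with Aquantile.

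The procedure was tested on simulated data for the mutant against wild type comparison, with 200 changed probes among 3098, a dye curve added, and spreads drawn from the fitted distribution. It recovered 89.6% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes in the right direction. Of the calls, 7.25% were unchanged probes, and the log2 size of 4-fold changes came out at 0.905 of the true one. The simulation held no dye effect specific to a probe. All simulated changes were 1.5-fold or larger, whereas most calls in the data were smaller. The rates therefore do not apply to those smaller differences. Noise was drawn for each probe separately, whereas in the data the differences between arrays were correlated between consecutive probe numbers (Spearman coefficient 0.264). The share of unchanged probes among calls also depends on how many probes change, and 995 were called in the data. The 7.25% is therefore not an estimate for the calls in the data.

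The rule for named items, also fixed before the data were examined, was the probes with the largest mean increase and decrease past the threshold with the same sign on both arrays; since no probe has a gene name, it was cut to 2 in each direction. Alternatives were other background corrections, other within-array normalizations, other filters on dim probes, the deposited value table, scaling of the arrays to the same spread, other variance models and thresholds, a separate-channel fit with the array as a block, and leaving out each array. Print-tip loess and a correlation without the 2 most extreme probes were added after seeing the data.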

Results

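The series asked how deletion of rsdA changes transcript levels in exponentially growing C. glutamicum R. RsdA is the anti-sigma factor of SigD, an extracytoplasmic-function sigma factor with targets in the synthesis of mycolic acids, the long-chain lipids of the outer cell envelope. The data consist of 2 arrays, each a direct comparison of 1 mutant RNA (Cy3) with 1 wild-type RNA (Cy5) from an independent experiment. Each of 3278 probes was measured at 2 spots per array. On array 1, 94.2% of the probes were well above background in the wild-type channel and 94.0% in the mutant channel. On array 2 the shares were 94.6% and 92.8%. The median wild-type intensity of the probe spots was 3030 and 3168 on arrays 1 and 2, against 139 and 151 at the empty spots. The median mutant intensity was 1376 and 1509, against 174 and 170 at the empty spots. Intensities given here are as scanned, before background correction and dye normalization, and the Cy5 channel was the brighter one on both arrays, so their quotients differ from the normalized ratios. The number of arrays, 2, limits the precision of all values given here.

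Deletion of rsdA was accompanied by a small set of large increases, fewer large decreases, and many small differences in both directions. In all, 44 probes were at least 2-fold higher in the mutant on both arrays, and 7 were at least 2-fold lower on both. If the arrays had been independent, 0.961 and 0.0742 probes would have been expected. The excess shows only that ratios repeat between the arrays. A dye effect specific to a probe would repeat too, since the mutant was in Cy3 on both. The count of 7 was 11 with normexp at offset 0, with processed signals followed by loess and in the deposited value table, and on array 1 alone 48 probes were at least 2-fold higher and 23 lower. At a 4-fold limit, 13 probes were higher and 3 were lower on both arrays. All 51 of the 2-fold probes also passed limma's adjusted p threshold of 0.05. That test used the same log2 ratios, so it is not separate support.

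The strongest increase was that of probe ID_2154, which rose 11.04-fold (mean log2 ratio 3.46, SD 0.269, n = 2 arrays, limma adjusted p = 0.0014). Its log2 ratio was 3.27 on array 1 and 3.65 on array 2, and its mutant intensity as scanned, before normalization, of 90033 and 94747 compared with 25261 and 18775 in the wild type. Probe ID_3149 rose 7.45-fold (mean log2 ratio 2.90, SD 0.260, n = 2, limma adjusted p = 0.0018), with log2 ratios of 2.71 and 3.08. Both probes were well above background in both channels on both arrays.

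The largest decrease was that of probe ID_765, whose fitted level was 105-fold lower in the mutant (limma adjusted p = 0.00059). The size is uncertain, because the mutant channel was at background. Raising its mutant level, where lower, to the lowest mutant level of any probe well above background left the fold at 105. That step therefore gave no separate lower bound. Its wild-type intensity before normalization was 23126 and 21002. Its mutant intensity of 176.5 and 159.75 lay beside local backgrounds of 173.5 and 167.5, and the mutant channel was well above background at 1 of its 2 spots on array 1 and at 0 on array 2. The fitted log2 ratio of -6.71 therefore rests on the background correction. The fitted fold ran from 61.0-fold with no background correction to 308-fold with processed signals followed by loess. A probe of the deleted gene would also read background in the mutant. Whether ID_765 is such a probe is unknown, since no probe is paired with a gene. Probe ID_2550 was the next, 10.3-fold lower in the mutant (mean log2 ratio -3.37, SD 0.237, n = 2, limma adjusted p = 0.0012). Before normalization its wild-type intensity was 109738 and 136407 and its mutant intensity 4734 and 4986, and both channels were well above background on both arrays.

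Among all 3098 probes tested, 995 passed the adjusted p threshold in limma with 508 higher and 487 lower in the mutant. Median centring in place of loess gave 842 higher and 878 lower, with 30 of the 814 calls shared by both settings changing sign, and a limma fit without variance moderation called 0 (605 probes at an unadjusted p under 0.05). Most of these differences were small. The median size was 1.27-fold among the higher and 1.22-fold among the lower probes, and 411 of the higher and 459 of the lower ones were under 1.5-fold. When limma's treat test asked for a change beyond 1.5-fold, 46 probes were higher and 8 were lower. The small differences cannot be separated from dye effects specific to a probe, since mutant RNA was in Cy3 on both arrays.

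**Figure D1:**
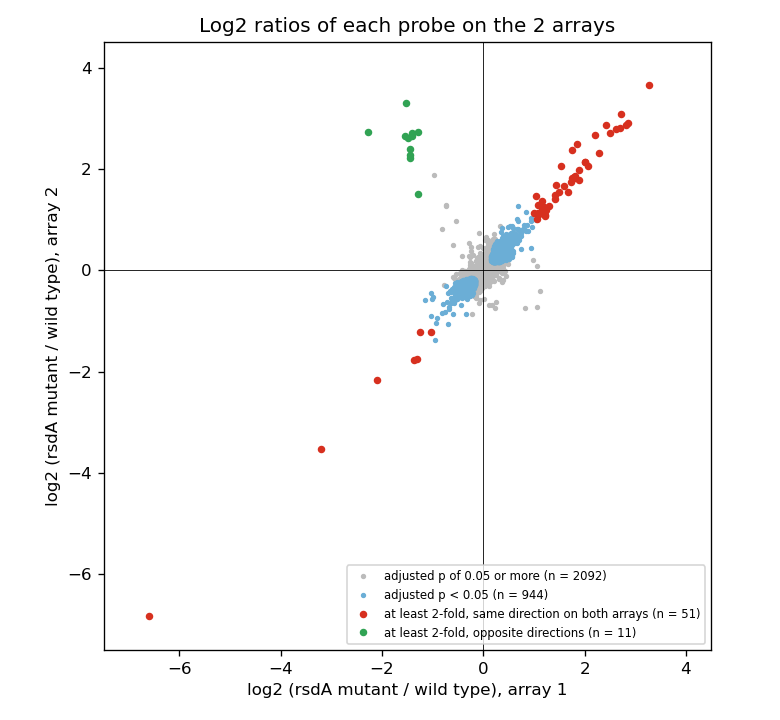
Log2 ratio of mutant over wild type on array 2 (y axis) against array 1 (x axis), 1 point for each of the 3098 probes tested, coloured by limma adjusted p and by size. The 44 probes at least 2-fold higher and the 7 at least 2-fold lower on both arrays (red) lie along the diagonal, and 11 probes (green) lie at least 2-fold from 0 in opposite directions, all lower on array 1 and higher on array 2.

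The 2 arrays ran in the same direction. Across the probes tested, Pearson's r between their log2 ratios was 0.706 and Spearman's coefficient was 0.796. Without the 2 probes with the largest mean log2 ratio in size, Pearson's r was 0.665. These are correlations across probes, which are not independent replicates. A dye effect specific to a probe would raise them too, since the mutant was in Cy3 on both arrays. The median absolute difference between the arrays, each value a mean over the spots of a probe, was 0.0747 on the log2 scale. Between the 2 single spots of a probe it was 0.0382 and 0.0363 within arrays 1 and 2. The 2 measures are not alike, since averaging over spots lowers spot noise only in the first. A group of 11 probes departed from this agreement: they were at least 2-fold lower in the mutant on array 1 and at least 2-fold higher on array 2, where 0.615 probes in opposite directions would be expected from independent arrays.

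**Figure D2:**
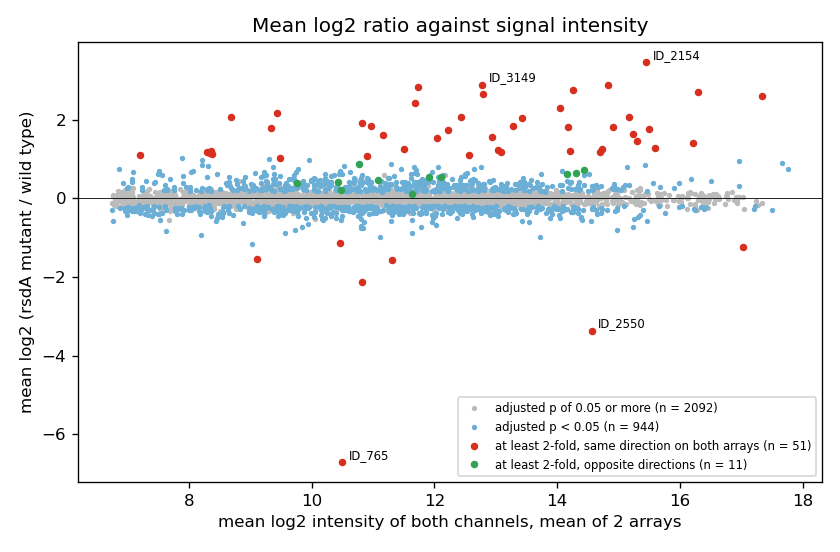
Mean log2 ratio of mutant over wild type over the 2 arrays (y axis) against the mean log2 intensity of both channels (x axis), 1 point for each of the 3098 probes tested, coloured by limma adjusted p and by size. The 4 named probes are labelled; ID_2154 is at 3.46, ID_765 is drawn at its fitted value of -6.71 although its mutant channel was at background, and the 2-fold probes (red) are spread over the range of intensities.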

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

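A probe marked as a control in the scanner files and not used in the comparison, ID_3288, gave signal above all empty spots of its array in both channels. Its wild-type (Cy5) intensity was 892 on array 1 and 609 on array 2, where the brightest empty spot was at 157.5 and 165, and its log2 ratio of mutant over wild type was -0.42 and -0.16. What this probe targets is not given in the sources used here.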

How the results depend on the processing

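The 4 named probes kept their direction under each alternative that gave them a value, and passed the threshold under each tested one except the fit without variance moderation; ID_765 has no value where both channels must be well above background. That fit called 0 probes higher and 0 lower in limma, with 1 residual degree of freedom and an unadjusted p under 0.05 for 605 probes. In place of 508 higher and 487 lower, median centring gave 842 and 878, and 30 of its 814 calls shared with the loess result had the opposite sign. The 2 settings differ only in that loess removes a trend of the ratios with intensity and median centring does not. What gave rise to that trend was not tested. An adjusted p of 0.01 gave 79 and 24, the treat test against 1.5-fold gave 46 and 8, and the processed signals without loess gave 322 lower. The count of probes at least 2-fold lower on both arrays went from 7 to 11 with processed signals followed by loess, to 11 with normexp at offset 0, and to 11 in the deposited value table; all 51 probes at least 2-fold changed were among that table's 62. A 4-fold limit gave 13 higher and 3 lower. With 1 array alone there is no test: 48 to 62 probes were at least 2-fold higher and 10 to 23 lower, the 23 on array 1. The separate-channel fit, the array kept as a block, gave 639 and 622. Each probe number has 1 probe, but whether several numbers belong to the same gene is unknown. No rule for several probes of a gene was therefore applied, and the gene list tests were not run. Dim probes lose ratio size to the offset.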

Other observations

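The counts of neighbouring probe numbers, the comparison of channels for the probes that differed between arrays, and the tests on the normalization of the excess of increases and on the distance between probe numbers were chosen after the patterns were seen; the tests on slide position, signal intensity, dye, spot defects and differences between the experiments were written down before their results were seen. Probe numbers that follow one another tended to share their direction. Of the 44 probes at least 2-fold higher on both arrays, 26 had a neighbouring number also in that set, in 10 runs of which the longest held 5, where chance placement gave a mean of 1.17 (permutation p = 0.0001 from 10000 draws, the smallest they can give). Of the 7 lower probes, 2 were neighbours, against a chance mean of 0.0234 (permutation p = 0.01). The largest decrease, that of ID_765, stood directly after a probe that rose 6.53-fold (log2 ratios 2.62 and 2.80, limma adjusted p = 0.001), the sixth largest increase, and directly before one with log2 ratios of -0.53 and -0.33 (limma adjusted p = 0.025).

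Over all 2948 pairs of consecutive numbers, the Spearman correlation between mean log2 ratios was 0.362 (bootstrap 95% interval 0.326 to 0.399; Pearson's r 0.252), a correlation across probes. Closeness on the slide does not account for it: the correlation was 0.360 (0.312 to 0.409) over the 1508 pairs whose spots lay at least 10 rows or columns apart, and 0.0482 between spots printed side by side. Consecutive numbers lay a median of 11 positions apart, so a position effect that recurs at a regular spacing was not tested. Similar signal intensity does not account for the correlation, since shuffling ratios within 20 intensity classes gave 0.0368 at the upper end of the 95% range of 1000 shuffles. A candidate explanation is that the numbers follow the chromosome, so that neighbours share an operon. The correlation fell to 0.232, 0.149 and 0.0644 at distances of 2, 3 and 5 numbers and to 0.0185 at 10. Without a map of the probes this explanation stays open, as does whether neighbouring numbers belong to the same gene.

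The probes at least 2-fold changed on both arrays were mostly higher in the mutant, 86.3% of 51. With array 1 alone the share was 67.6%. The excess stayed under each of the other background corrections and normalizations tried, where the lowest share was 81.0%. Each of those settings normalized the dyes or had ratios centred near 0, so an imbalance shared by all of them was not tested. A dye effect stays open, because 0 arrays had the opposite dye orientation. Loss of an anti-sigma factor, which the design names, is a biological explanation and was not tested, since no probe is paired with a gene.

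In all, 14 probes differed between the arrays by more than 2 on the log2 scale, by 3.94 in the median, and all 14 had the higher ratio on array 2. Single spot defects do not account for them, as the 2 spots of such a probe differed within an array by 0.0417 in the median. Both channels moved from array 1 to array 2. The wild-type level of all 14 was lower, by a median log2 difference of -1.24, and the mutant level of all 14 was higher, by 2.62. Selecting probes by the difference in ratio set the gap between these movements in advance, but not how it was divided between the channels. Of the 14, 9 had a neighbouring number in the set, against a chance mean of 0.105 (permutation p = 0.0001, the smallest that 10000 draws can give). Over all probes the differences between arrays were correlated between consecutive numbers (Spearman coefficient 0.264, 0.225 to 0.298). Between probes side by side at the 1 spot used for position, the coefficient was lower (0.0584, 0.0223 to 0.0951). A candidate explanation is RNA that differed between the 2 experiments in both strains, in opposite directions. A position effect that recurs at a regular spacing was not tested for these differences either. Whether growth, genetic differences between cultures or handling was behind them stays open, as does what the neighbouring numbers have in common.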
